A study of Homo sapiens with 16 samples.

How the data were processed

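RNA from human epidermal keratinocytes was measured on 16 Affymetrix arrays for human genes, which read each gene with 1 or more probe sets of short oligonucleotides. The labels put 4 arrays in each of 4 groups: untreated cells, cells given PD98059 at 50 uM, cells given SB203580 at 15 uM, and cells given a mixture of these inhibitors with SP600125, whose dose is stated as 5 uM. The doses in the mixture are not stated separately from those of the inhibitors on their own. Each group has 1 array at 1, 4, 24 and 48 h. Arrays of cells given SP600125 alone were not analysed here.

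The deposited table holds log2 expression values with similar array medians, taken here as already normalized between arrays. The log2 scale was read from the values, which run from 2.17 to 12.8, with array medians between 3.84 and 3.92. The submitters' processing notes name MAS5 and GCOS, Affymetrix software for making probe set signals, without a version or a role. The background correction, the normalization and the summary of probes are not given in the sources used here, so their effect on the values is open. A summary that shrinks dim signals, for example, would make the differences of weakly expressed genes too small. Arrays give no read depth, and their number limits the precision.

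Each array was shifted so that its mean over probe sets, leaving out the highest and lowest 2% of values, equalled that of all arrays. The shifts ran from -0.046 to 0.082, and no pseudocount was added. The table has 22277 probe sets, of which 62 are controls. The annotation pairs 19064 probe sets with 1 gene and 1043 with several, and it does not list 2108. Only probe sets with 1 gene were used. Gene symbols were checked through their gene numbers: 12 numbers were not found in the reference table and 0 symbols changed. Probe sets had to lie at or above the median of their array on at least 4 arrays, which 12063 did. For the 2290 genes with several such probe sets, the probe set with the highest mean was used, and their mean was an alternative. This left 7410 genes. No pair of arrays held identical values.

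Tests were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over the 7410 genes and a threshold of 0.05. The model for all times held the group and the time point and left 9 residual degrees of freedom. The model for the early part (1 and 4 h) and the late part (24 and 48 h) let each group's effect differ between the parts and left 6. All 16 arrays shared 1 estimate of the spread, so a wide spread in 1 group also affects the calls in the other groups. The time point is the only replicate: the labels name parallel controls at each time, and nothing says that arrays came from separate cultures or donors, so p-values measure only the spread between these arrays. No test was made at a single time point. The labels place the untreated arrays in an experiment named I and give no experiment for the treated arrays, so a difference of experiment between treatments is open, while an offset of the untreated arrays would enter each comparison with untreated cells alike.

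Time points paired the groups because the labels name parallel controls. As a check, deviations of arrays from their group means correlated across genes at a mean r of 0.241 for the 24 pairs of arrays at the same time (from -0.162 to 0.629) and -0.0799 for the 72 pairs at different times. The time point was therefore a block in each comparison of groups, and a fit without it was an alternative.

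The 33 gene lists, the comparisons and the rule for named genes were fixed before the data were examined. The lists were ERK targets and feedback, EGF receptor ligands and regulators, AP-1 subunits, cytokines and chemokines, interferon response, epidermal differentiation and cornified envelope, basal keratinocyte and hemidesmosome, activated and simple epithelial keratins, desmosome and tight junction, DNA replication and G1/S, mitosis and G2/M, p53 targets, cholesterol synthesis, fatty acid and epidermal lipid metabolism, glycolysis and hypoxia, NRF2 targets, aryl hydrocarbon receptor targets, unfolded protein and ATF4 response, heat shock, splicing factors, ribosome biogenesis, cytosolic ribosomal proteins, proteasome, oxidative phosphorylation, matrix remodelling and migration, TGF-beta targets, Notch pathway, lysosome and autophagy, antimicrobial peptides, and markers of melanocytes, fibroblasts, immune and Langerhans cells, and endothelium. The 30 lists with at least 3 tested members were compared with all other genes by camera with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Of 121 calls made with the preset correlation, 0 held with the estimated one, where the smallest adjusted p was 0.0511. Members were also adjusted over the list alone.

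Named genes are up to 10 in each direction for each treatment over all times, and up to 5 for other comparisons, with the largest change among genes past the threshold and the same sign at each time used. Where a direction had none, the 3 genes with the smallest p were taken. Up to 4 members of each list with the smallest p were added, and so were the kinases that the inhibitors act on. Genes outside this rule are said to be so where they appear. The kinases MAPK14 and MAPK8 were not analysed here.

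The procedure was tested in 5 simulations with 200 of 7410 genes changed. For PD98059 over all times it recovered 95.8% of genes changed by 1 log2 unit and 100% by 2, with 4.3% of calls false. For the mixture late these were 86.8%, 100% and 5.56%. Real effects may be fewer and vary over time, so recovery may be lower. For the overlap of calls, 20 simulations drew each gene's values from its fitted spread with no difference between groups, and took as many genes of smallest p per direction as had passed. In 20 simulations of PD98059 over all times, a list shifted by 0.5 was called 20 times, and 2 of 580 tests of other lists were called. The simulated genes varied independently. These counts leave out correlation between genes and do not give the rate of false list calls in the data. For late against early, with deviations shared by the arrays of a time point, of the size estimated from the 4 time points, 53.2% of calls were false with arrays as units and 5.93% with time points as units.

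Alternatives were quantile normalization, median centring, pseudocounts of the 25th percentile of linear values (9.62) divided by 10 and multiplied by 4, no filter or a stricter one, the mean of a gene's probe sets, a variance trend with robust estimation, no block for the time point, leaving out each array or time point, and using only the groups compared. The unshifted deposited values and array quality weights (limma's arrayWeights) were added after the data were seen. So was a fit of late against early on the means over groups at the 4 time points, since arrays of the same time correlate.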

Results

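Gene expression was followed in human epidermal keratinocytes, the main cell type of the outer layer of skin, during inhibition of the MAP kinase pathways. Cells were kept in a basal medium without growth supplements for 24 h and were then left untreated or given PD98059, which blocks activation of ERK by the MEK kinases, SB203580, which inhibits the p38 kinases, or a mixture of both with SP600125, which inhibits the JNK kinases. Each of the 4 groups was measured on 1 array at 1, 4, 24 and 48 h, so n = 4 per group over the time course. There were 2 arrays per group in the early part (1 and 4 h) and in the late part (24 and 48 h). Array medians lay between 3.84 and 3.92 on the log2 scale. Differences are given in log2 units with the standard error (SE) of the limma fit.

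The SB203580 array at 1 h stood apart in its control signals. Its probe sets at the 5' end of ACTB and GAPDH read 7.80 and 7.74, against 11.2 to 12 and 10.3 to 11 on the other 15 arrays. The 3' minus 5' difference was 2.88 for ACTB and 3.52 for GAPDH, against -1.18 to -0.40 and 0.32 to 0.90 elsewhere. Its median Spearman correlation with the other arrays was 0.905, against 0.932 to 0.959 for the others. Markers of other skin cell types were low: medians were 3.33 for melanocyte, 3.48 for fibroblast, 3.31 for immune and Langerhans and 3.55 for endothelial markers, against 8.68 for basal keratinocyte genes. The highest of these were SPARC, THY1 and COL1A1 on the fibroblast list, at 7.51, 5.55 and 5.42.

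**Figure D1:**
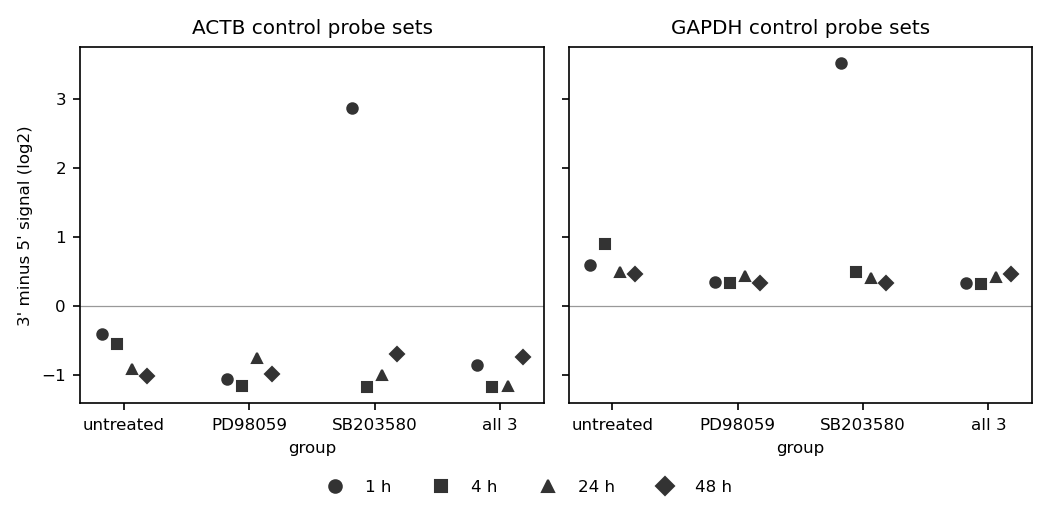
Difference between the 3' and 5' control probe sets (log2, vertical axis) of ACTB (left) and GAPDH (right) on each of the 16 arrays, by group (horizontal axis) and time (symbol). The SB203580 array at 1 h lies at 2.88 and 3.52, above the other 15 arrays.

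PD98059 was compared with untreated cells over all times to find transcripts that depend on the ERK pathway. EFNA1, a cell-surface ligand of Eph receptors, rose by 1.20 ± 0.17 (SE, 2.30-fold, limma, adjusted p = 0.0266) and was higher at all 4 time points. CAMK2N1, an inhibitor of calcium/calmodulin-dependent kinase II, fell by 0.75 ± 0.11 (adjusted p = 0.0319) and was lower at all 4. These 2 genes, 1 higher and 1 lower, were the only ones of 7410 past the threshold, while 314 had an unadjusted p under 0.05. All 18 measured members of the list of ERK targets and feedback were below 0, with a median of -0.84: 0 passed over all genes and 11 passed as lower adjusted over the list alone (camera, adjusted p = 2.83e-23, adjusted p = 0.0813 with an estimated correlation). Among them FOSL1, an AP-1 subunit, differed by -1.28 ± 0.26 and SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling, by -1.39 ± 0.31, neither past the threshold over all genes. The list of mitosis and G2/M had 25 of 28 members below 0, 0 of them past the threshold, with a median of -0.26 (camera, adjusted p = 1.38e-06, adjusted p = 0.717 with an estimated correlation). The list of unfolded protein and ATF4 response had 13 of 18 members above 0, 0 past the threshold, with a median of 0.17 (camera, adjusted p = 0.0308, adjusted p = 0.775 with an estimated correlation). Its median was -0.05 without the untreated 4 h array. The gene count was 0 without the PD98059 1 or 24 h array, the SB203580 48 h array or the untreated 4, 24 or 48 h array, 1 without the PD98059 48 h or SB203580 24 h array. It was 4 without the PD98059 4 h array, 5 and 6 without the mixture's 4 h and 1 h arrays, and 8 without the untreated 1 h array. It was 0 without time as a block, 4 with a variance trend, 5 with the arrays of these 2 groups alone and 12 with array weights. With a time point left out it was 1 without the 1 h or 4 h arrays and 0 without the 24 h or 48 h arrays. Neither EFNA1 nor CAMK2N1 passed without any 1 of the 4 time points.

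In the early part, ERK target genes and ligands of the EGF receptor were lower with PD98059, but 0 genes passed over all genes (limma, 448 at an unadjusted p under 0.05). The ERK targets and feedback list had a median of -1.22, with 17 of 18 members below 0, 0 past the threshold over all genes and 14 passing as lower adjusted over the list alone (camera, adjusted p = 1.03e-22, adjusted p = 0.107 with an estimated correlation). DUSP6, a cytoplasmic ERK phosphatase, differed by -2.38 ± 0.42, SPRY2 by -1.53 ± 0.24 and SPRY4 by -1.97 ± 0.37. By time, the median of this list was -1.77 at 1 h, -0.76 at 4 h, -0.67 at 24 h and -0.34 at 48 h. The list of EGF receptor ligands and regulators had 4 of 5 members below 0, 0 past the threshold and 2 lower adjusted over the list alone (camera, adjusted p = 0.00247, adjusted p = 0.107 with an estimated correlation). These were TGFA, a ligand of the receptor, at -1.03 ± 0.19, and HBEGF, another ligand, whose difference was -1.76 ± 0.39. The list of cholesterol synthesis had 12 of 17 members above 0, 0 past the threshold, and a median of 0.24 (camera, adjusted p = 0.00247, adjusted p = 0.107 with an estimated correlation). MVD, mevalonate diphosphate decarboxylase, stood at 0.88 ± 0.26. The unfolded protein and ATF4 response list had 15 of 18 members above 0, 0 past the threshold and 1 higher adjusted over the list alone (camera, adjusted p = 0.000453, adjusted p = 0.855 with an estimated correlation). Its median was 0.005 at 1 h and 0.54 at 4 h. The genes with the smallest p were TBX3, a T-box transcription factor, at -1.36 ± 0.19 (adjusted p = 0.0534), and EDN1, the vasoconstrictor peptide endothelin, at 1.30 ± 0.22 (adjusted p = 0.0929). The count rose from 0 to 10 without the mixture's 1 h or 4 h array, 14 without the untreated 4 h array, and 20 and 21 without the SB203580 4 h and 1 h arrays. It was 1 with the mean of probe sets, 2 with a variance trend, 91 with array weights and 134 with the arrays of these 2 groups alone.

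**Figure D2:**
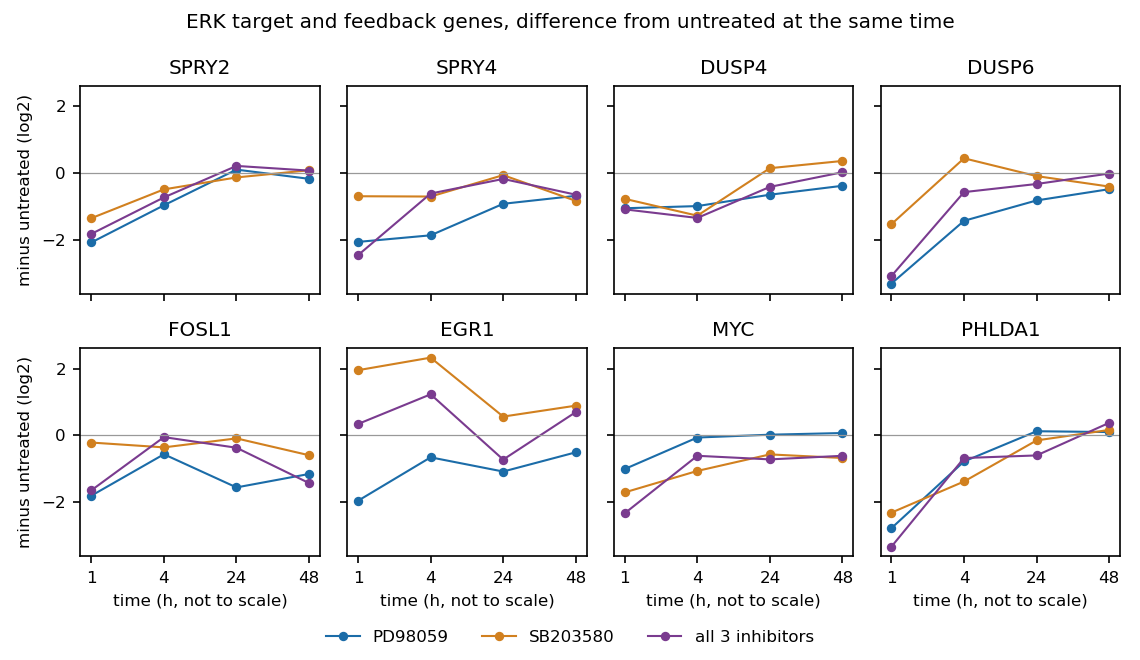
Difference from untreated at the same time (log2, vertical axis) of 8 genes of the ERK list against time in h (horizontal axis, not to scale), with a line per treatment and 1 array per point. SPRY2, SPRY4 and DUSP6 are lowest at 1 h under PD98059 and the mixture, and EGR1 lies above 0 under SB203580.

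In the late part, PD98059 was compared with untreated cells at 24 and 48 h. TAGLN, an actin-binding protein of contractile cells, rose by 2.73 ± 0.29 (limma, adjusted p = 0.00144), EDN1 by 2.08 ± 0.22 (adjusted p = 0.00144). MYLK, myosin light chain kinase, rose by 1.97 ± 0.33 (adjusted p = 0.0295). TNFAIP3, an inhibitor of NF-kB signalling, rose by 1.57 ± 0.20 and TNC, the matrix protein tenascin, by 1.55 ± 0.23. MMP1, interstitial collagenase, fell by 2.89 ± 0.33 (adjusted p = 0.00185), AQP3, a water and glycerol channel, by 1.79 ± 0.21 (adjusted p = 0.00257). SERPINB1, an inhibitor of neutrophil proteases, fell by 1.64 ± 0.23 (adjusted p = 0.00899). PYGB, a glycogen phosphorylase, fell by 1.67 ± 0.30 and ISG20, an exonuclease induced by interferon, by 1.62 ± 0.28. The same sign at 24 and 48 h was a condition for naming these 10 genes. In the 16 fits without 1 array, the calls of MYLK, ISG20 and PYGB were kept in 6, 6 and 7. In total 18 genes passed, 10 higher and 8 lower, and 675 had an unadjusted p under 0.05. The count was 1 without the PD98059 24 h array, 4 without the untreated 24 or 48 h array, 7 without the PD98059 1 or 4 h array, 8 without the SB203580 24 or 48 h array. It was 38, 49 and 54 without the PD98059 48 h, SB203580 1 h and SB203580 4 h arrays. It was 8 without time as a block, 10 after quantile normalization, 11 with no filter or with the stricter one, 5 with the larger pseudocount, 36 with a variance trend and 245 with the arrays of these 2 groups alone.

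Mitosis genes were lower late with PD98059. All 28 members of the mitosis and G2/M list were below 0, with a median of -0.52: 1 fell over all genes, CDC20, an activator of the anaphase-promoting complex, by 1.35 ± 0.21 (limma, adjusted p = 0.0229), and 14 passed as lower adjusted over the list alone (camera, adjusted p = 3.83e-17, adjusted p = 0.274 with an estimated correlation). The median was -0.82 at 24 h and -0.22 at 48 h. The list of activated and simple epithelial keratins had 6 of 7 members below 0, 0 past the threshold and 2 lower adjusted over the list alone (camera, adjusted p = 0.00218, adjusted p = 0.537 with an estimated correlation). KRT18, a simple epithelial keratin, stood at -0.75 ± 0.18. The TGF-beta targets had 7 of 11 members above 0, with TAGLN past the threshold over all genes and 3 higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.037, adjusted p = 0.537 with an estimated correlation). The lists of epidermal differentiation and of DNA replication and G1/S had medians of -0.18 and -0.15 with 0 members past the threshold (camera, adjusted p = 0.037 and 0.0375, adjusted p = 0.878 and 0.906 with an estimated correlation). By time these medians were -0.03 and -0.33 at 24 h and -0.35 and 0.12 at 48 h. Without the untreated 48 h array the differentiation median was 0.04, and without the untreated 24 h array the replication median was 0.12. In the test of late against early effects of PD98059, 0 genes passed (limma, 771 at an unadjusted p under 0.05), TAGLN being nearest at 2.88 ± 0.41 (adjusted p = 0.0713). The mitosis list differed by a median of -0.54 (camera, adjusted p = 4.94e-10, adjusted p = 0.519 with an estimated correlation). The AP-1 subunits differed by 0.45, with 9 of 11 members above 0 and 0 past the threshold (camera, adjusted p = 0.0452, adjusted p = 0.702 with an estimated correlation). MAFF, a small Maf protein, stood at 2.48 ± 0.74. DNA replication and G1/S differed by -0.15 (camera, adjusted p = 0.0452, adjusted p = 0.783 with an estimated correlation), and by 0.04 without the untreated 24 h array. The count of this difference was 1 without the PD98059 24 h, untreated 24 h, or SB203580 1 or 4 h array and 6 without the untreated 4 h array. It was 1 with a variance trend, 3 with array weights and 286 with the arrays of these 2 groups alone.

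SB203580 was compared with untreated cells over all times to find transcripts that depend on p38, and 0 genes passed (limma, 631 at an unadjusted p under 0.05, 1 gene with a variance trend, 7 with array weights). The smallest p belonged to ALDH1A3, a retinaldehyde dehydrogenase, at -1.06 ± 0.16 (adjusted p = 0.064), INHBA, a subunit of activin, at -1.46 ± 0.28 (adjusted p = 0.231) and JUND, an AP-1 subunit, at 0.85 ± 0.18 (adjusted p = 0.262). Of 30 lists 11 passed, each as lower, and 0 held with an estimated correlation, where the smallest adjusted p was 0.123. Those with the largest medians were the aryl hydrocarbon receptor targets, 4 of 5 below 0 with a median of -0.45 (camera, adjusted p = 0.00258, adjusted p = 0.123 with an estimated correlation), and the ERK targets and feedback. Of the latter 15 of 18 were below 0, with a median of -0.32 (camera, adjusted p = 0.00258, adjusted p = 0.56 with an estimated correlation). At 1, 4, 24 and 48 h the aryl hydrocarbon receptor median was -0.97, 0.28, -0.18 and -0.61 and the ERK median -0.67, -0.26, -0.05 and -0.12. Without the SB203580 1 h array, whose 5' control signals were low, they were -0.20 and -0.44 over all times (camera, adjusted p = 0.0217 and 0.00192). The matrix remodelling and migration list had 19 of 24 members below 0, 0 past the threshold (camera, adjusted p = 0.00258, adjusted p = 0.363 with an estimated correlation). THBS1, a matrix protein that binds TGF-beta, stood at -1.0 ± 0.24. The splicing factors had a median of -0.09 (camera, adjusted p = 0.0245, adjusted p = 0.575 with an estimated correlation) that became 0.02 without that array (adjusted p = 0.866). Interferon response, desmosome and tight junction, heat shock and TGF-beta targets, also among the 11, did not pass without it either (camera, adjusted p = 0.121, 0.365, 0.113 and 0.151). Epidermal differentiation, basal keratinocyte, ribosome biogenesis and matrix remodelling did (camera, adjusted p = 0.0203, 0.037, 0.0382 and 0.0203). The gene count was 1 without the SB203580 1 h, PD98059 24 h or mixture's 24 h array, 1 without shifting the arrays, and 1 without the 1 h or 48 h arrays.

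In the early part, 3 genes of the unfolded protein and ATF4 response list rose with SB203580. TXNIP, an inhibitor of thioredoxin, rose by 2.31 ± 0.29 (limma, adjusted p = 0.0058), EGR1, an immediate early transcription factor, by 2.14 ± 0.32 (adjusted p = 0.0128). GADD45B, a stress-induced gene, rose by 1.5 ± 0.17 (adjusted p = 0.0058). DDIT3, the transcription factor CHOP, rose by 2.11 ± 0.34 (adjusted p = 0.022), ATF4, the main transcription factor of the integrated stress response, by 1.27 ± 0.17 (adjusted p = 0.00708). CHAC1, an enzyme that degrades glutathione, rose by 1.61 ± 0.31 (adjusted p = 0.0441). IL1A, an interleukin-1 cytokine, fell by 2.27 ± 0.31 (adjusted p = 0.00708) and IL1B fell by 2.07 ± 0.28 (adjusted p = 0.00708). SOX9, a transcription factor of epithelial progenitors, fell by 2.23 ± 0.28, INHBA by 1.97 ± 0.35 and NET1, an activator of RhoA, by 1.71 ± 0.25. In the 16 fits without 1 array, the calls of CHAC1 and INHBA were kept in 2 and 4. In total 28 genes passed, 8 higher and 20 lower, and 1280 had an unadjusted p under 0.05. The split was 6 higher and 9 lower after quantile normalization, and 6 higher and 31 lower in the unshifted values. One of the 2 early SB203580 arrays is the 1 h array with the 3' minus 5' differences of 2.88 and 3.52. Without it 49 genes passed, among them 22 of the 28, with only the 4 h array left in the group, and with array weights 0 passed. The count was 5 without the untreated 1 h array, 10, 11 and 14 without the untreated 24, 48 and 4 h arrays, 15 without any of the PD98059 1 and 4 h, SB203580 24 and 48 h or mixture's 24 and 48 h arrays and 714 without the SB203580 4 h array. It was 14 without time as a block, 9 with the larger pseudocount and 5 with the arrays of these 2 groups alone.

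The unfolded protein and ATF4 response list had 13 of 18 members above 0 early with SB203580, of which 3 rose over all genes and 5 adjusted over the list alone (camera, adjusted p = 0.0119, adjusted p = 0.669 with an estimated correlation). Its median was -0.05 at 1 h and 0.72 at 4 h. Among ERK targets and feedback 14 of 18 were below 0: EGR1 rose and DUSP4, a nuclear MAP kinase phosphatase, fell by 1.03 ± 0.18 (limma, adjusted p = 0.0351, kept in 3 of the 16 fits without 1 array), and 1 was higher and 4 lower adjusted over the list alone (camera, adjusted p = 0.00753, adjusted p = 0.669 with an estimated correlation). The splicing factors had 27 of 37 members below 0 and 0 past the threshold (camera, adjusted p = 0.00241, adjusted p = 0.669 with an estimated correlation). HNRNPH1, an RNA-binding regulator of splicing, stood at -1.03 ± 0.35. The heat shock list had 9 of 11 below 0, 0 past the threshold and 3 lower adjusted over the list alone (camera, adjusted p = 0.0237, adjusted p = 0.669 with an estimated correlation). BAG3, a co-chaperone, stood at -0.67 ± 0.21. Ribosome biogenesis had 16 of 21 members below 0, 0 past the threshold and 2 lower adjusted over the list alone (camera, adjusted p = 0.0237, adjusted p = 0.685 with an estimated correlation). Its median was 0.18 at 1 h and -0.41 at 4 h. DDX21, a nucleolar RNA helicase, stood at -1.73 ± 0.37. Desmosome and tight junction had 10 of 14 below 0 and 0 past the threshold (camera, adjusted p = 0.0237, adjusted p = 0.669 with an estimated correlation), with medians of -0.46 at 1 h and -0.06 at 4 h. Without the 1 h array with low 5' control signals, the splicing factors, heat shock and desmosome and tight junction lists did not pass (camera, adjusted p = 0.415, 0.196 and 0.679), with medians of -0.13 each against -0.31, -0.19 and -0.38 with it. The unfolded protein and ATF4 response, ERK and ribosome biogenesis lists passed without it (camera, adjusted p = 5.24e-09, 0.000317 and 0.00527).

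In the late part, 2 genes of the epidermal differentiation and cornified envelope list fell with SB203580, and so did 2 of the unfolded protein and ATF4 response list, which concerns the endoplasmic reticulum (ER). SPRR1A, a precursor of the cornified envelope, fell by 2.61 ± 0.25 (limma, adjusted p = 0.000809) and S100A8, a subunit of the antimicrobial protein calprotectin, by 2.62 ± 0.34 (adjusted p = 0.00605). CRELD2, an ER stress protein, fell by 1.5 ± 0.17 (adjusted p = 0.00289), PDIA4, a disulfide isomerase, by 1.27 ± 0.15 (adjusted p = 0.00289), SDF2L1, an ER chaperone subunit, by 1.47 ± 0.24 (adjusted p = 0.0373). P3H2, a collagen prolyl hydroxylase, fell by 1.43 ± 0.18 (adjusted p = 0.00605). ALDH1A3 fell by 1.26 ± 0.20 (adjusted p = 0.0339) and SERPINE2, a protease inhibitor of the matrix, by 0.91 ± 0.16 (adjusted p = 0.0454). In total 10 genes passed as lower, among them HYOU1 and FKBP11, further ER folding factors named after their values were seen. As higher 0 passed, and 400 genes had an unadjusted p under 0.05. In the 16 fits without 1 array, the calls of SDF2L1, ALDH1A3 and SERPINE2 were kept in 4, 4 and 2. Nearest among higher genes was MAP1B, a microtubule-associated protein, at 1.23 ± 0.23 (adjusted p = 0.088). The count was 1 without the SB203580 48 h or untreated 48 h array, 2 without the untreated 24 h array, 5 without any PD98059 array, the mixture's 1 or 4 h array or the untreated 1 or 4 h array. It was 6 without the SB203580 24 h array and 23 without the SB203580 1 or 4 h array. It was 6 without time as a block, 6 after quantile normalization, 5 with the larger pseudocount, 19 with array weights and 0 with the arrays of these 2 groups alone.

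Of the epidermal differentiation list, 21 of 28 members were below 0 late with SB203580, of which 2 fell over all genes and 5 adjusted over the list alone (camera, adjusted p = 1.56e-08, adjusted p = 0.198 with an estimated correlation). Its median was -0.04 at 24 h and -0.39 at 48 h. All 6 antimicrobial peptides were below 0 (median -0.74): S100A8 fell over all genes and 3 adjusted over the list alone (camera, adjusted p = 6.21e-08, adjusted p = 0.159 with an estimated correlation). Both lists hold PI3, S100A8, S100A9 and SLPI, a protease inhibitor at -0.99 ± 0.20, so these results overlap. The basal keratinocyte and hemidesmosome list had 12 of 16 below 0, 0 past the threshold and 5 lower adjusted over the list alone (camera, adjusted p = 0.000314, adjusted p = 0.159 with an estimated correlation). The median was -0.06 at 24 h and -0.33 at 48 h. COL7A1, the collagen of anchoring fibrils, stood at -0.79 ± 0.20. In the unfolded protein and ATF4 response list, the ER chaperones PDIA4 and SDF2L1 fell over all genes and 4 adjusted over the list alone, while 7 of 18 were above 0 (camera, adjusted p = 7.6e-05, adjusted p = 0.419 with an estimated correlation). Matrix remodelling and migration had 16 of 24 below 0, with SERPINE2 past the threshold and 5 lower adjusted over the list alone (camera, adjusted p = 7.6e-05, adjusted p = 0.419 with an estimated correlation). The matrix median was 0.005 at 24 h and -0.34 at 48 h. The mitosis and G2/M list had a median of 0.16, 21 of 28 above 0 and 0 past the threshold (camera, adjusted p = 0.0429, adjusted p = 0.8 with an estimated correlation). This median was -0.02 without the untreated 48 h array. The activated and simple epithelial keratins had a median of -0.11 and 0 past the threshold (camera, adjusted p = 0.0404, adjusted p = 0.57 with an estimated correlation). It was 0.04 at 24 h, -0.26 at 48 h, and 0.08 over the late part without the SB203580 48 h array.

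The late effect of SB203580 minus its early effect passed for 2 genes: SPRR1A at -2.72 ± 0.35 and CRELD2 at -1.85 ± 0.24 (limma, adjusted p = 0.0144 for both, 861 genes at an unadjusted p under 0.05). The unfolded protein and ATF4 response list differed by a median of -0.63, with 17 of 18 members below 0, 0 past the threshold and 7 lower adjusted over the list alone (camera, adjusted p = 5.34e-07, adjusted p = 0.674 with an estimated correlation). DDIT3 stood at -2.18 ± 0.48. The splicing factors differed by 0.27, with 31 of 37 above 0 and 0 past the threshold (camera, adjusted p = 0.00141, adjusted p = 0.674 with an estimated correlation). The early side of these differences includes the 1 h array with low 5' control signals, without which 8 genes passed. The splicing factors then did not pass, with a median of 0.22 (camera, adjusted p = 0.159), while the unfolded protein and ATF4 response list did, with a median of -1.08 (camera, adjusted p = 1.53e-15). The count was 0 without the SB203580 48 h array, the mixture's 1 h array or the untreated 1, 4 or 48 h array, 1 without the SB203580 24 h array, and 360 without the SB203580 4 h array. It was 1 with the mean of probe sets and 0 with the arrays of these 2 groups alone.

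**Figure D3:**
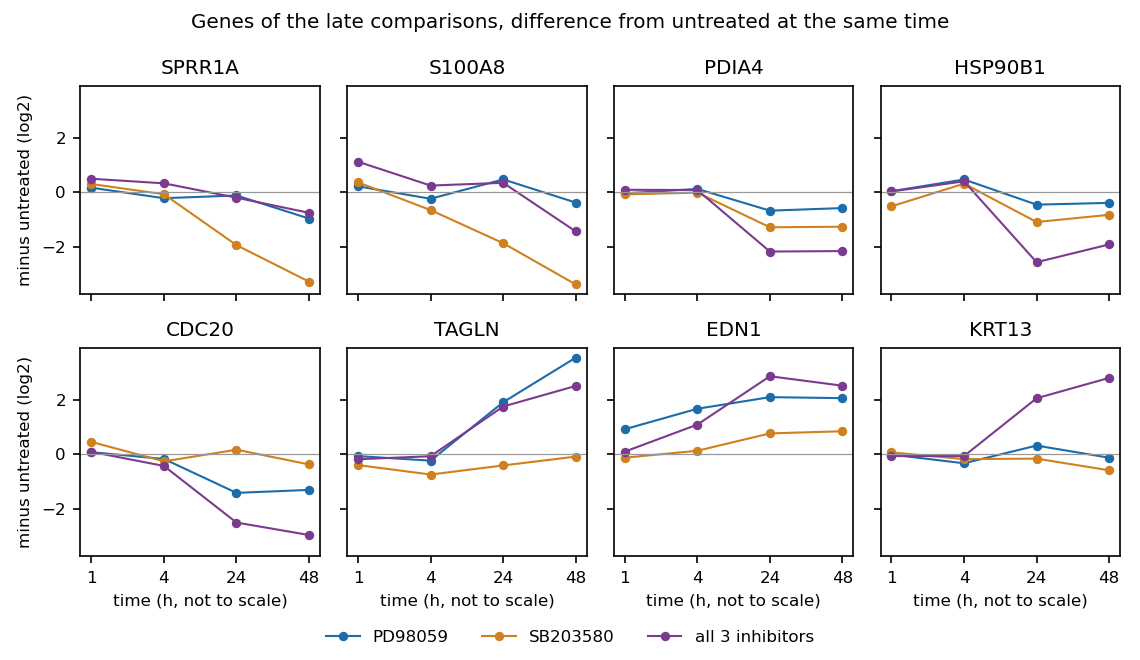
Difference from untreated at the same time (log2, vertical axis) of 8 genes of the late comparisons against time in h (horizontal axis, not to scale), with a line per treatment and 1 array per point. SPRR1A and S100A8 are lowest under SB203580 at 48 h, and PDIA4, HSP90B1 and CDC20 are lowest under the mixture at 24 and 48 h.

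The mixture of all 3 inhibitors changed 4 genes over all times. The histone genes H2AC6 and H2BC5 rose by 2.44 ± 0.33 (limma, adjusted p = 0.0159) and 1.15 ± 0.18 (adjusted p = 0.026). DKK1, a secreted Wnt antagonist, fell by 1.14 ± 0.17 and ZMYND8, a chromatin reader, by 1.04 ± 0.15 (adjusted p = 0.0159 for both). Each had the same sign at all 4 time points, and 659 genes had an unadjusted p under 0.05. All 28 mitosis and G2/M genes were below 0, 0 past the threshold and 16 lower adjusted over the list alone (camera, adjusted p = 1.92e-17, adjusted p = 0.304 with an estimated correlation). CENPE, a kinetochore motor, stood at -0.58 ± 0.12. Interferon response had 18 of 23 members below 0, 0 past the threshold and 4 lower adjusted over the list alone (camera, adjusted p = 2.42e-05, adjusted p = 0.304 with an estimated correlation). Cytosolic ribosomal proteins had 22 of 25 members above 0, 0 past the threshold, with a median of 0.08 (camera, adjusted p = 0.0375, adjusted p = 0.582 with an estimated correlation). The gene count was 0 without the mixture's 4, 24 or 48 h array or the untreated 4 or 24 h array, 2 without the untreated 48 h array, 10 without the SB203580 4 h array and 11 without the untreated 1 h array. It was 0 with the larger pseudocount, 2 without time as a block, 8 with the arrays of these 2 groups alone and 24 with array weights, 1 without the 24 h arrays and 0 without the 48 h arrays.

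In the early part, 2 genes of the unfolded protein and ATF4 response list rose with the mixture, CHAC1 and ATF4. CHAC1 rose by 2.51 ± 0.31 (limma, adjusted p = 0.0136), H2AC6 by 2.43 ± 0.39 (adjusted p = 0.0293), STC2, a secreted glycoprotein induced by stress, by 1.49 ± 0.26 (adjusted p = 0.0351), ATF4 by 1.29 ± 0.17 (adjusted p = 0.0137). GADD45B rose by 1.04 ± 0.17 (adjusted p = 0.0312). ADAMTS1, a matrix metalloprotease, fell by 1.91 ± 0.26 (adjusted p = 0.0147), SOX9 by 1.81 ± 0.28 (adjusted p = 0.0219), IL1B by 1.60 ± 0.28, RHOB, a small GTPase, by 1.38 ± 0.23. TBX3 fell by 1.35 ± 0.19. In the 16 fits without 1 array, the calls of STC2, IL1B and RHOB were kept in 3 each and that of GADD45B in 5. In total 14 genes passed, 5 higher and 9 lower, and 461 had an unadjusted p under 0.05. The unfolded protein and ATF4 response list had 16 of 18 members above 0, of which 2 rose over all genes and 5 adjusted over the list alone (camera, adjusted p = 7.49e-11, adjusted p = 0.318 with an estimated correlation). ERK targets and feedback had 15 of 18 below 0 and a median of -1.05, of which DUSP4 fell by 1.22 ± 0.18 (adjusted p = 0.0186), with 1 higher and 11 lower adjusted over the list alone (camera, adjusted p = 1e-13, adjusted p = 0.318 with an estimated correlation). By time it was -1.77 at 1 h and -0.39 at 4 h. The Notch pathway had 10 of 11 below 0, 0 past the threshold and 1 lower adjusted over the list alone (camera, adjusted p = 0.0123, adjusted p = 0.47 with an estimated correlation): JAG1, a Notch ligand, at -1.07 ± 0.27. The count was 0 without the mixture's 1 h array, 6 without the untreated 1 h array, 7 without the PD98059 1 or 4 h, SB203580 48 h or untreated 24 or 48 h array. It was 8 without the PD98059 24 or 48 h array, and 62 and 61 without the SB203580 1 and 4 h arrays. It was 5 with the larger pseudocount, 7 without time as a block, 8 with no filter, 22 with a variance trend and 120 with array weights.

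In the late part, the mixture changed 146 genes, 63 higher and 83 lower, with 1029 at an unadjusted p under 0.05. EDN1 rose by 2.70 ± 0.22 and HCAR3, a receptor for hydroxy fatty acids, by 2.60 ± 0.22 (limma, adjusted p = 3.24e-05 for both). H2AC6 rose by 2.45 ± 0.39 (adjusted p = 0.00639), KRT13, a keratin of moist stratified epithelia, by 2.44 ± 0.25 (adjusted p = 0.000148) and TAGLN by 2.14 ± 0.29 (adjusted p = 0.00164). SCG5, a secretory granule chaperone, fell by 2.73 ± 0.37 (adjusted p = 0.00158), CDC20 by 2.72 ± 0.21 (adjusted p = 3.24e-05) and LPXN, a focal adhesion adaptor, by 2.41 ± 0.22 (adjusted p = 7.06e-05). Among the genes of the lists, TNFAIP3 rose by 1.56 ± 0.20 and CLDN4, a tight junction claudin, by 1.25 ± 0.23. These genes had the same sign at 24 and 48 h. Median centring gave 41 higher and 93 lower. The count was 32 without the untreated 24 h array, 61 and 66 without the mixture's 48 and 24 h arrays, 67 without the untreated 48 h array, 96 without the mixture's 1 or 4 h array. It was 294 and 298 without the SB203580 1 and 4 h arrays and 64 without time as a block.

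Mitosis genes were lower late with the mixture. All 28 mitosis and G2/M members were below 0, with a median of -0.96, of which 12 fell over all genes and 26 adjusted over the list alone (camera, adjusted p = 2.94e-34, adjusted p = 0.0511 with an estimated correlation). PRC1, a midzone microtubule bundler, fell by 1.83 ± 0.20 (limma, adjusted p = 0.000283), CCNB2, a mitotic cyclin, by 1.49 ± 0.20 (adjusted p = 0.00141). UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, fell by 1.38 ± 0.18 (adjusted p = 0.00111). The median was -1.08 at 24 h and -0.69 at 48 h. The DNA replication and G1/S list had 26 of 31 below 0 and a median of -0.45, of which 3 fell over all genes and 7 adjusted over the list alone (camera, adjusted p = 3.61e-09, adjusted p = 0.415 with an estimated correlation). Its median was -0.82 at 24 h and -0.12 at 48 h. The genes that fell over all genes were RRM2, a subunit of ribonucleotide reductase, which fell by 2.2 ± 0.21 (adjusted p = 7.45e-05), and MCM5 and MCM7, subunits of the replicative helicase, which fell by 1.29 ± 0.24 and 1.28 ± 0.28. The p53 targets had 12 of 13 above 0, of which 2 rose over all genes and 4 adjusted over the list alone (camera, adjusted p = 0.000224, adjusted p = 0.067 with an estimated correlation). GADD45A, a stress-induced growth arrest gene, rose by 1.01 ± 0.21 and SESN1, a stress-induced regulator of metabolism, by 0.92 ± 0.18.

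Of other lists, 4 members of the unfolded protein and ATF4 response list and 5 of the interferon response list fell late with the mixture. HSP90B1, an ER chaperone of the HSP90 family, fell by 2.24 ± 0.21 (limma, adjusted p = 7.45e-05), SDF2L1 by 2.32 ± 0.24 (adjusted p = 0.000182), PDIA4 by 2.16 ± 0.15 (adjusted p = 1.71e-05). HSPA5, the main ER chaperone, fell by 1.63 ± 0.22 (adjusted p = 0.00151). These were the 4 members of the unfolded protein and ATF4 response list that fell over all genes, while 1 rose and 8 of 18 were above 0 (camera, adjusted p = 0.0128, adjusted p = 0.559 with an estimated correlation). The median of that list was -0.07 at 24 h and -0.29 at 48 h. Interferon response had 17 of 23 below 0, of which 5 fell over all genes and 14 adjusted over the list alone (camera, adjusted p = 3.28e-09, adjusted p = 0.156 with an estimated correlation). IFITM1, a membrane protein that restricts virus entry, fell by 1.56 ± 0.17 (adjusted p = 0.000227), MX1, an antiviral GTPase, by 1.32 ± 0.22 (adjusted p = 0.00774), ISG20 by 1.62 ± 0.28. OAS3, a sensor of double-stranded RNA, fell by 1.23 ± 0.22. Matrix remodelling and migration had 2 members that rose and 5 that fell (camera, adjusted p = 0.00296, adjusted p = 0.511 with an estimated correlation): SERPINE2 fell by 1.71 ± 0.16, MMP10, stromelysin 2, by 1.60 ± 0.31 and THBS1 by 1.40 ± 0.27. The matrix list median was 0.02 at 24 h and -0.61 at 48 h. Ribosome biogenesis had 17 of 21 members below 0, 1 past the threshold and 2 lower adjusted over the list alone (camera, adjusted p = 0.00139, adjusted p = 0.513 with an estimated correlation). Its median was -0.48 at 24 h and 0.05 at 48 h. FBL, a nucleolar methyltransferase, fell by 0.79 ± 0.17. Cytokines and chemokines had 6 of 8 members above 0, TNFAIP3 past the threshold and 3 higher adjusted over the list alone (camera, adjusted p = 0.0268, adjusted p = 0.511 with an estimated correlation). Their median was 0.66 at 24 h and -0.04 at 48 h. The basal keratinocyte and hemidesmosome list had 12 of 16 members below 0, with 1 higher and 4 lower adjusted over the list alone (camera, adjusted p = 0.0439, adjusted p = 0.415 with an estimated correlation). Its median was -0.19 at 24 h and -0.36 at 48 h. Over all genes KRT15, a basal keratin, rose by 1.06 ± 0.17, and PDPN, a membrane glycoprotein, fell by 0.99 ± 0.23, a call kept in 6 of the 16 fits without 1 array. DLK2 and ITGB4 of this list stood at -0.74 ± 0.21 and -0.87 ± 0.27. Desmosome and tight junction had 12 of 14 members above 0, of which 2 rose over all genes (camera, adjusted p = 0.0421, adjusted p = 0.431 with an estimated correlation). The splicing factors had 27 of 37 below 0 and 0 past the threshold (camera, adjusted p = 0.00296, adjusted p = 0.511 with an estimated correlation), with medians of -0.38 at 24 h and 0.10 at 48 h.

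The late effect of the mixture minus its early effect passed for 25 genes, 10 higher and 15 lower, with 759 at an unadjusted p under 0.05. HCAR3 differed by 2.65 ± 0.31 and NEFL, a neurofilament subunit, by 2.25 ± 0.27 (limma, adjusted p = 0.00196 for both), KRT13 by 2.49 ± 0.35 (adjusted p = 0.00529) and EDN1 by 2.10 ± 0.31 (adjusted p = 0.00787). PDIA4 differed by -2.25 ± 0.21 (adjusted p = 0.000674), CDC20 by -2.56 ± 0.30 (adjusted p = 0.00196), HSP90B1 by -2.45 ± 0.30 (adjusted p = 0.00221) and SDF2L1 by -2.58 ± 0.34 (adjusted p = 0.00424). The mitosis list differed by a median of -0.80, with 4 genes past the threshold and 18 adjusted over the list alone (camera, adjusted p = 3.06e-25, adjusted p = 0.111 with an estimated correlation). The unfolded protein and ATF4 response list differed by -0.79, with 4 past the threshold and 9 adjusted over the list alone (camera, adjusted p = 7.63e-12, adjusted p = 0.185 with an estimated correlation). Proteasome genes differed by -0.22, with 20 of 25 below 0 and 0 past the threshold (camera, adjusted p = 0.00599, adjusted p = 0.545 with an estimated correlation). Median centring moved the median of all genes from 0.056 to -0.069 and gave 7 higher and 18 lower. The count was 7 and 10 without the mixture's 1 and 24 h arrays, 15 without the untreated 24 h array, 16 without the PD98059 1 or 4 h or mixture's 48 h array. It was 79 and 82 without the SB203580 1 and 4 h arrays, 13 with the larger pseudocount, 16 without time as a block and 84 with array weights.

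**Figure D4:**
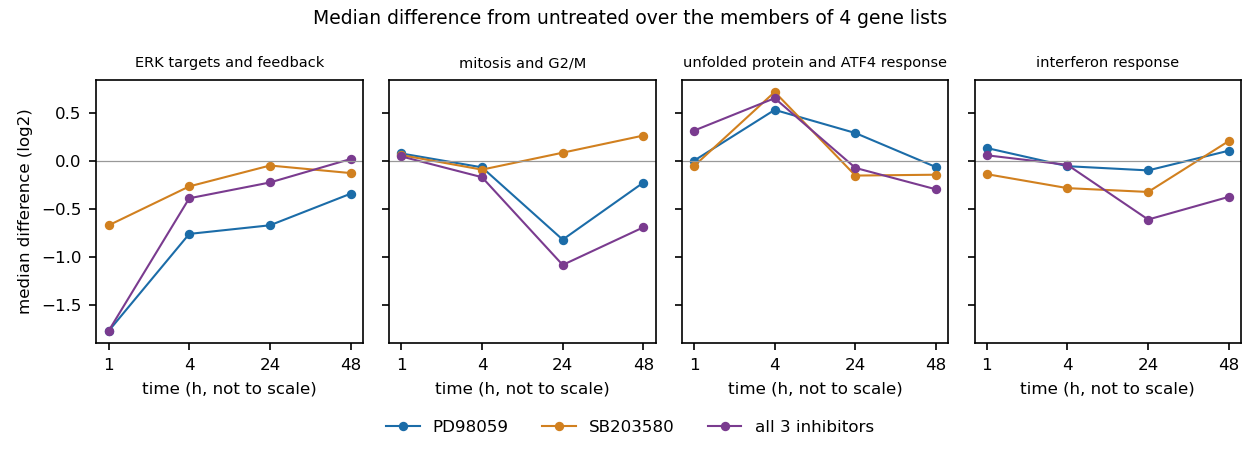
Median difference from untreated at the same time (log2, vertical axis) over the members of 4 gene lists against time in h (horizontal axis, not to scale), with a line per treatment and 1 array per point. The ERK list lies at -1.77 at 1 h under PD98059 and under the mixture, and the mitosis list lies at -0.82 and -1.08 under these treatments at 24 h and at 0.09 under SB203580.

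PD98059 and SB203580 were compared with each other over all times, which uses no untreated array in the difference. EFNA1 was higher with PD98059 by 1.60 ± 0.17 and DUSP10, a phosphatase of p38 and JNK, by 1.19 ± 0.13 (limma, adjusted p = 0.00047 for both). HSPB1, a small heat shock protein phosphorylated downstream of p38, was higher by 1.34 ± 0.22 (adjusted p = 0.0346). EGR1 was lower with PD98059, at -2.49 ± 0.34 (adjusted p = 0.00588), and so was IER2, an immediate early gene, at -1.24 ± 0.20 (adjusted p = 0.0233). These 5 genes, 3 higher and 2 lower, were the ones past the threshold, and 795 had an unadjusted p under 0.05. Of ERK targets and feedback, 16 of 18 were lower with PD98059, 2 past the threshold, with 1 higher and 6 lower adjusted over the list alone (camera, adjusted p = 4.6e-05, adjusted p = 0.474 with an estimated correlation). All 28 mitosis genes were lower with PD98059, 0 past the threshold, with a median of -0.31 (camera, adjusted p = 4.62e-05, adjusted p = 0.574 with an estimated correlation). TGF-beta targets had 8 of 11 members above 0, 0 past the threshold and 3 higher adjusted over the list alone (camera, adjusted p = 0.00104, adjusted p = 0.379 with an estimated correlation). INHBA stood at 1.25 ± 0.28. The count was 3 without the PD98059 1 or 24 h or SB203580 24 h array, 8 without the mixture's 1 h or untreated 1 h array, and 10 without the SB203580 1 h array. It was 2 with the larger pseudocount, 3 with no filter, 8 with the arrays of these 2 groups alone, 14 without the 1 h arrays, 3 without the 24 h arrays and 30 with array weights.

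The mixture's effect was set against the sum of the PD98059 and SB203580 effects. The difference holds SP600125's effect, non-additivity and, reversed in sign, any offset of untreated arrays, which the design cannot separate. Over all times 0 genes passed (limma, 244 at an unadjusted p under 0.05). The smallest p belonged to ADM, the peptide adrenomedullin, at -1.29 ± 0.32, and PPL, the cornified envelope protein periplakin, at 0.94 ± 0.24 (adjusted p = 0.998 for both). Of ERK targets and feedback, 18 of 18 lay above the sum, with a median of 0.59 and 0 past the threshold (camera, adjusted p = 1.21e-08, adjusted p = 0.238 with an estimated correlation). Of epidermal differentiation genes 23 of 28 lay above it, 0 past the threshold and 3 higher adjusted over the list alone (camera, adjusted p = 1.02e-05, adjusted p = 0.238 with an estimated correlation). S100A9 stood at 1.07 ± 0.29. Mitosis genes lay below it, with a median of -0.35 and 0 past the threshold (camera, adjusted p = 1.02e-05, adjusted p = 0.582 with an estimated correlation).

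The late part of the time course was compared with the early part over all 4 groups, with the group as a block. The difference is a mean over untreated and treated arrays, so it mixes time with treatment effects that differ between the parts. It is not the change of untreated cells. CDC20 and LPXN, for example, had late minus early effects of -2.56 and -2.34 under the mixture. In all 635 genes passed, 226 higher and 409 lower, with 1724 at an unadjusted p under 0.05. MCM5 fell by 1.47 ± 0.17 (limma, adjusted p = 0.000245), GINS2, a helicase subunit, by 1.35 ± 0.13 (adjusted p = 0.000126), CDC20 by 1.61 ± 0.28 (adjusted p = 0.00278), RRM2 by 1.54 ± 0.23 (adjusted p = 0.00147). LPXN fell by 1.76 ± 0.24 (adjusted p = 0.000829). Of 31 DNA replication genes 24 fell over all genes and 26 adjusted over the list alone (camera, adjusted p = 3.09e-20, adjusted p = 0.143 with an estimated correlation). Of 28 mitosis genes 25 fell over all genes and 28 adjusted over the list alone (camera, adjusted p = 3.22e-25, adjusted p = 0.143 with an estimated correlation). Interferon response had 9 of 23 members that fell, and 1 higher and 11 lower adjusted over the list alone (camera, adjusted p = 4.98e-05, adjusted p = 0.262 with an estimated correlation), among them IFI35, an interferon-induced leucine zipper protein, by 0.76 ± 0.12. DUSP6 rose by 1.32 ± 0.28 (adjusted p = 0.00867), TMEM158, a gene induced by Ras signalling, by 1.22 ± 0.19 (adjusted p = 0.00151). CA12, a carbonic anhydrase, rose by 1.18 ± 0.13 (adjusted p = 0.000245). Glycolysis and hypoxia had 6 of 23 members that rose and 0 that fell (camera, adjusted p = 4.79e-05, adjusted p = 0.143 with an estimated correlation), with NDRG1, a hypoxia-induced gene, up by 0.86 ± 0.12. NRF2 targets had 3 of 14 that rose and 0 that fell (camera, adjusted p = 0.0147, adjusted p = 0.152 with an estimated correlation), among them AKR1C2, an aldo-keto reductase, by 0.53 ± 0.11. The p-values of this comparison take the arrays of a part as independent, although each part holds 2 time points and arrays of the same time correlated. With the time point as the unit, the mean over groups at 24 and 48 h against that at 1 and 4 h, 31 genes passed, 13 higher and 18 lower, of which 29 were among the 635. MCM5, LPXN, DUSP6, TMEM158 and CA12 then passed, while GINS2, CDC20, RRM2, IFI35, NDRG1 and AKR1C2 did not. Of DNA replication genes 3 then fell, of mitosis genes 0 and of interferon response genes 1 (camera, adjusted p = 1.15e-16, 6.51e-16 and 0.000107, adjusted p = 0.334, 0.399 and 0.487 with an estimated correlation). Of glycolysis and hypoxia genes and NRF2 targets 0 then passed (camera, adjusted p = 0.000223 and 0.0576, adjusted p = 0.334 and 0.429 with an estimated correlation). With arrays as units the count was 391, 416 and 416 without the mixture's 4, 1 and 24 h arrays, and 1457 with array weights.

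The genes of the kinases that the inhibitors act on did not pass in any comparison with untreated cells over all times. MAP2K1, the MEK kinase upstream of ERK, differed by -0.53 ± 0.11 with PD98059 (limma, adjusted p = 0.171), -0.28 ± 0.11 with SB203580 (adjusted p = 0.537) and -0.50 ± 0.11 with the mixture (adjusted p = 0.136). MAP2K2, MAPK3, MAPK9 and MAPK11 differed by between -0.26 and 0.21, and array or setting turned the sign of several of these small differences. The lists that passed in none of the comparisons were fatty acid and epidermal lipid metabolism, oxidative phosphorylation, lysosome and autophagy, and fibroblast markers, with lowest camera adjusted p of 0.123, 0.105, 0.0797 and 0.213.

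Responses to treatments sharing the untreated arrays were set side by side. Over 7410 genes, which are not independent replicates, effects over all times correlated at 0.285 for PD98059 and SB203580, 0.696 for PD98059 and the mixture and 0.444 for SB203580 and the mixture, against 0.499, 0.5 and 0.498 in simulations without any effect. The covariances were 0.0115, 0.0303 and 0.0217, against 0.0142, 0.0143 and 0.0142 in the simulations. With 2 separate untreated arrays per treatment, of different times, mean correlations over 6 assignments were -0.0155, 0.202 and 0.0411. The drop also holds differences between times. In the late part SB203580 and the mixture shared 8 of the genes that fell, among them ALDH1A3, CRELD2, PDIA4 and SDF2L1, where independent lists would share 0.11. In 20 simulations without any effect, with the same untreated arrays, as many genes of smallest p shared 3.55 on average and at most 6. PD98059 and the mixture shared 3 genes that rose late (EDN1, TAGLN and TNFAIP3) and 4 that fell (AQP3, CDC20, ISG20 and NOL6, a nucleolar protein), where independent lists would share 0.085 and 0.09 and the simulations 2.65 and 3.15, at most 7 and 6. Neither count exceeded the simulations' highest. In the early part SB203580 and the mixture shared 3 genes that rose (ATF4, CHAC1 and GADD45B) and 6 that fell (DKK1, DUSP4, IL1B, SIK1, SOX9 and TBX3), where independent lists would share 0.0054 and 0.024 and the simulations 0.65 and 1.55, at most 2 and 3. The simulations leave out real effects and the independent lists leave out the shared untreated arrays, so the excess over either does not measure a shared effect. Of genes past the threshold in the simulations, 0 were shared by these pairs. With 2 untreated arrays in each part these could not be split, and part of the excess may come from them.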

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

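The tests on the RNA of the SB203580 1 h array, on the untreated 1 h array and on other splits of the arrays were planned before their results were seen, while the tests on mitosis genes and on 4 ER chaperone genes were chosen after the result was seen.

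The SB203580 1 h array stood apart from its group in the 3' minus 5' difference of ACTB (2.88) and GAPDH (3.52). It also did in the probe set for 18S rRNA (6.21). There the untreated 48 h array, used in each late comparison with untreated cells, read 7.27 and all others 3.46 to 4.49. Of 100 genes with the largest SB203580 difference at 1 h, 33% had the same sign at 4 h (Wilson 95% interval 24.6 to 42.7). The share was 96% for PD98059 and 79% for the mixture. Degraded RNA on the SB203580 1 h array may be a source of part of the early SB203580 differences. An untreated 1 h array out of place would give these genes the same sign under the other treatments. This held for 50% under PD98059 and 52% under the mixture, which argues against that array as their main source. A smaller part stays open, since the SB203580 1 h array helped pick the genes. An effect of SB203580 limited to 1 h also stays open, because the group has no other array at 1 h.

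All 28 measured mitosis genes were below 0 late under PD98059, of which 1 passed the threshold. Late untreated arrays high in these genes would lower both the PD98059 and the SB203580 effects. The median of the PD98059 minus the SB203580 late effect was -0.65 over 28 members, and the untreated arrays cancel in it. It shows PD98059 arrays below SB203580 arrays and cannot tell whether the untreated arrays were high. Against these arrays the SB203580 median was 0.16, or -0.02 without the untreated 48 h array. High untreated arrays as the whole cause would need a rise of these genes under SB203580, which was not tested. RNA quality is argued against only by GAPDH and ACTB, whose larger 3' minus 5' excess of late PD98059 over late untreated arrays was 0.1. The median of -0.65 cannot speak to an offset of the experiment named for the untreated arrays either, since these arrays cancel in it. Treated arrays carry no such label, so a difference of experiment between treatments stays open. An effect of PD98059 stays open as a hypothesis whose mechanism was not tested, and the call on the list is lost with an estimated correlation.

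Of the 18 measured members of the unfolded protein and ATF4 response list, HSP90B1, HSPA5, PDIA4 and SDF2L1, all ER chaperones, fell late under the mixture, and PDIA4 and SDF2L1 also under SB203580, where HSP90B1 stood at -0.96 ± 0.21 (SE, limma, adjusted p = 0.197) and HSPA5 at -0.82 ± 0.22 (adjusted p = 0.381). Above 0 were 7 of 18 members under SB203580 (camera, adjusted p = 7.6e-05, adjusted p = 0.419 with an estimated correlation) and 8 under the mixture (adjusted p = 0.0128, adjusted p = 0.559 with an estimated correlation). The 4 genes, picked because they fell under the mixture, had medians of -1.11 under SB203580, -2.20 under the mixture and -0.37 under PD98059. This argues against late untreated arrays high in these genes as the whole cause under the mixture, unless PD98059 raised the genes. The larger 3' minus 5' excess of these treatments' late arrays was 0.12, which argues against RNA quality by this measure. With the same limit, the PD98059 median argues against an offset of the experiment named for the untreated arrays as the whole cause under the mixture. A difference of experiment between treatments stays open, as does an effect of SB203580, a hypothesis whose mechanism was not tested.

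The 18S rRNA probe set on the mixture's 48 h array read 4.23, apart from the other 3 arrays of the group. INHBA differed by -2.86 under SB203580 at 4 h, apart from the differences at the other 3 times. Of 72 groups of 4 values tested in this way 5 stood apart, and chance gives about 1 in 20. Late and early effects of SB203580 differed by test for SPRR1A (-2.72) and CRELD2 (-1.85). Those of the mixture differed for HCAR3 (2.65), KRT13 (2.49), TAGLN (2.25, kept in 5 of the 16 fits without 1 array), NEFL (2.25), EDN1 (2.10), SDF2L1 (-2.58), CDC20 (-2.56), HSP90B1 (-2.45), LPXN (-2.34) and PDIA4 (-2.25).

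Other splits of the arrays into groups of the same sizes were compared with the real one. Arrays are paired by time, and splits that break the pairing are not equivalent to the real one. The planned bound of 5% of all splits was thus wrong for this design. The 8 splits with 1 array of each time on either side keep the pairing and are too few for a share under 0.05. Over all times the real split gave 2 genes for PD98059, 4 for the mixture and 5 for PD98059 against SB203580, and no other of the 8 gave any. Over all 35 splits, 1 gave as many in each case, and the highest other gave 1, 0 and 0. For SB203580 over all times and for the mixture minus the sum the real count was 0, so that 35 of 35 and 100 of 100 splits had to give as many and the comparison decides nothing. The highest other splits gave 8 and 3. The split with 8 put the 1 and 4 h arrays of both groups together. With time as a block, what it reflects was not tested. For late against early the real split gave 635 and the highest other 0, with 1 of 99 as large, but the 4 time points allow only 3 splits into pairs of times, too few for a share under 0.05.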

How the results depend on the processing

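The values without a shift of the arrays, with array quality weights and with the time point as the unit, and all gene list medians without 1 array, were chosen after the data were seen. Counts of genes moved by over 1.5 times in 63 fits with another setting and stayed within this in 148, and without 1 array these were 113 and 143. Of the values for named genes past the threshold, 1614 kept their direction and their side of the threshold under settings other than leaving out 1 array, 312 kept the direction and lost the call, and 0 turned direction. Without 1 array these were 1955, 573 and 0. For the lists called, 1228 were kept, 118 lost the call and 0 turned direction, and without 1 array 1716, 213 and 7. Of named genes not past the threshold, 129 values (158 without 1 array) passed it under another setting. Where a group was left with 1 early or late array, that array was assumed to vary like the other groups. Except where the fit held fewer arrays or probe sets, the cause was not tested.

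Quantile normalization gave 15 genes for SB203580 early, 10 for PD98059 late and 6 for SB203580 late. The pseudocount of 4 times the 25th percentile gave 0 for the mixture over all times, 9 for SB203580 early, 5 for the mixture early, 5 for PD98059 late, 5 for SB203580 late, 13 for the mixture late minus early and 2 for PD98059 against SB203580. With no filter on dim probe sets there were 8 for the mixture early, 11 for PD98059 late and 3 for PD98059 against SB203580, and with the stricter filter 11 for PD98059 late. The mean of a gene's probe sets gave 1 for PD98059 early and 1 for SB203580 late minus early. A variance trend with robust estimation gave 4 for PD98059 and 1 for SB203580 over all times, 2 for PD98059 early, 22 for the mixture early, 36 for PD98059 late and 1 for PD98059 late minus early. With no shift there was 1 for SB203580 over all times. With the time point as the unit late against early gave 31, of which 29 were among the 635, in a fit of 4 means with 2 residual degrees of freedom. With an estimated correlation 0 gene lists were called.

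The fit without the time point as a replicate block, which drops the pairing, gave 0 for PD98059 and 2 for the mixture over all times, 14 for SB203580 early, 7 for the mixture early, 8 for PD98059 late, 6 for SB203580 late, 64 for the mixture late and 16 for the mixture late minus early.

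Array weights gave 12 for PD98059, 7 for SB203580 and 24 for the mixture over all times, 91 for PD98059 early, 0 for SB203580 early, 120 for the mixture early, 19 for SB203580 late, 3 for PD98059 and 84 for the mixture late minus early, 30 for PD98059 against SB203580 and 1457 for late against early. Only the arrays of the groups compared gave 5 for PD98059 and 8 for the mixture over all times, 134 for PD98059 early, 5 for SB203580 early, 245 for PD98059 late, 0 for SB203580 late, 286 for PD98059 and 0 for SB203580 late minus early, and 8 for PD98059 against SB203580. Without the 1 h arrays there were 1 for PD98059, 1 for SB203580 and 14 for PD98059 against SB203580, without the 4 h arrays 1 for PD98059, without the 24 h arrays 0 for PD98059, 1 for the mixture and 3 for PD98059 against SB203580, and without the 48 h arrays 0 for PD98059, 1 for SB203580 and 0 for the mixture.

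Without each array in turn, counts over all times ranged from 0 to 8 for PD98059, 0 to 1 for SB203580 and 0 to 11 for the mixture. Early they ranged from 0 to 21, 5 to 714 and 0 to 62, late from 1 to 54, 1 to 23 and 32 to 298, and late minus early from 0 to 6, 0 to 360 and 7 to 82, in the same order. They ranged from 3 to 10 for PD98059 against SB203580 and from 391 to 827 for late against early. List medians that turned direction ranged from -0.048 to 0.365 for the unfolded protein and ATF4 response under PD98059 over all times, -0.161 to 0.022 for splicing factors under SB203580 over all times, -0.441 to 0.039 for epidermal differentiation and -0.34 to 0.121 for DNA replication under PD98059 late, -0.448 to 0.04 for DNA replication under PD98059 late minus early, and -0.334 to 0.08 for activated keratins and -0.023 to 0.312 for mitosis under SB203580 late.

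Small differences of kinase genes over all times, and 1 of TNFRSF10B, turned direction. Without each array in turn, the PD98059 difference ranged from -0.134 to 0.076 for MAPK3, -0.089 to 0.048 for MAPK11 and -0.009 to 0.133 for MAPK9, the SB203580 difference from -0.334 to 0.187 for MAP2K2, -0.071 to 0.269 for MAPK11 and -0.001 to 0.282 for MAPK9, and that of the mixture from -0.334 to 0.1 for MAP2K2, -0.045 to 0.165 for MAPK3 and -0.133 to 0.101 for MAPK11. MAPK11 under PD98059 was 0.014 with median centring, 0.001 with the larger pseudocount, 0.036 with the mean of probe sets, 0.01 with array weights, 0.027 without the 1 h arrays and 0.041 without the 4 h arrays. The mean of probe sets gave -0.04 for MAPK9 under PD98059, 0.053 for MAP2K2 and 0.015 for MAPK11 under the mixture, and -0.058 for TNFRSF10B in the mixture's late minus early effect. Array weights gave 0.04 for MAPK3 under PD98059. Without the 1 h arrays MAPK11 was -0.024 under SB203580 and 0.059 under the mixture. Without the 4 h arrays MAP2K2 was 0.01 under SB203580 and MAPK3 -0.018 under the mixture, and without the 24 h arrays the latter was -0.003. Without the 48 h arrays MAPK3 was 0.07 and MAPK9 -0.016 under PD98059, and MAP2K2 was 0.233 under SB203580 and 0.119 under the mixture.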

Other observations

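The values of this paragraph, except that of TGFBI under SB203580, lie outside the rule for named genes, which takes NEFL and MAP1B for other comparisons. They were chosen after they were seen, and both tests on histone genes and on the ERK list were chosen after the result was seen. Late with the mixture, ACTA2, smooth muscle actin, rose by 1.26 ± 0.20 (SE, limma, adjusted p = 0.00639) and SVIL, an actin-binding membrane protein, by 1.13 ± 0.24 (adjusted p = 0.0302). NEFL rose by 2.04 ± 0.19 (adjusted p = 7.06e-05) and MAP1B by 1.23 ± 0.23 (adjusted p = 0.0181). KLF4, a transcription factor of epidermal barrier formation, rose by 1.09 ± 0.21 (adjusted p = 0.0192) and ASS1, argininosuccinate synthase, by 1.79 ± 0.41 (adjusted p = 0.0459). NRG1, a ligand of ERBB receptors, fell by 1.31 ± 0.23 (adjusted p = 0.0102) and PROCR, the protein C receptor, by 1.14 ± 0.25 (adjusted p = 0.0395). TGFBI, a matrix protein induced by TGF-beta, fell by 1.14 ± 0.23 (adjusted p = 0.0214), and its difference under SB203580 was -1.24 ± 0.23 (adjusted p = 0.0653).

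Antimicrobial peptides differed between the late and the early effect of SB203580 by a median of -0.99, with 6 of 6 members below 0, 0 past the threshold over all genes and 4 lower adjusted over the list alone (camera, adjusted p = 8.73e-05, adjusted p = 0.674 with an estimated correlation). Aryl hydrocarbon receptor targets had a median of -0.70 late with the mixture, with 4 of 5 below 0, 1 of them past the threshold, and 1 higher and 3 lower adjusted over the list alone (camera, adjusted p = 0.0242, adjusted p = 0.253 with an estimated correlation).

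A hypothesis was that replication-dependent histone genes rise together where mitosis genes fall. Late with the mixture 12 of 13 measured histone genes were above 0, with a median of 0.62, but 11 of 13 were above 0 under PD98059 and under SB203580, with medians of 0.32 and 0.21. Since the share was also high under SB203580, where the mitosis list had a median of 0.16, the test leaves open whether these lists move together.

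Another hypothesis was that SB203580 and SP600125 in the mixture weaken the response of ERK targets to PD98059. The median of the ERK list lay closer to 0 under the mixture than under PD98059 at 3 of 4 time points (-0.39 against -0.76 at 4 h, -0.22 against -0.67 at 24 h and 0.02 against -0.34 at 48 h), while at 1 h both were -1.77. With 1 array at each time the test cannot decide, and no arrays of SP600125 alone were analysed here.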
